A study of Homo sapiens with 36 samples.

How the data were processed

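Chromatin accessibility was measured by ATAC-seq, in which a transposase inserts sequencing adapters into open chromatin, in 36 libraries of BT549, a triple-negative breast cancer cell line. Per the labels' protocols, about 25 M paired-end reads of 50 bp were aimed at per sample. The libraries fall into 10 groups in 3 experiments, and groups were taken from the sample titles, which number biological replicates. A second cell line named in the series design, MDA-MB-231, was not analysed here.

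The deposited files are peak lists, 1 per library, so the authors called peaks in each library on its own rather than on pooled replicates. Per the submitters' processing notes, bcl2fastq, SAMtools, MACS2 and HOMER were used and the build was GRCh38 (hg38). The aligner, the shifting of reads, the handling of duplicates and the settings of the peak caller are not given in the sources used here. For every peak the authors deposited a score, a fold enrichment at the summit over the background of the same library, and −log10 p and −log10 q values. The smallest deposited −log10 q in any library lay near 1.3, a q of 0.05. These values belong to the authors and to single peaks, and they were used to rank, filter or describe peaks within a list and to recover a background level that was compared between libraries.

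A peak list holds no read counts, so total depth per library is not known directly. The background level under a peak was recovered from the authors' fold and p in 3000 weak peaks per library, by finding the whole pileup and the background that give both values in a Poisson model within a tolerance of 0.002. All 3000 gave a whole pileup in each library, and the lowest background of a library, shared by 16.6 to 52.9% of these peaks, served as a measure of relative depth, since peaks above it carry a raised local background. It ranged from 0.492 to 0.677 in the experiment with siRNA against GATA6, from 0.235 to 0.319 in the experiment with BRM014, and from 0.242 to 0.335 in the experiment with siRNA against BRG1 and BRM. Counts of peaks were therefore compared within an experiment and not across experiments.

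Distinct peaks on chromosomes 1 to 22 and X were kept. Overlapping peaks of all libraries of an experiment were merged into regions, and a library held a region when a peak of it overlapped the region by at least 1 bp. This gave 204358 regions over 12 libraries, 189959 over 16 and 128681 over 8. A region was called gained when every library of the treated group and no library of the control group held it, and lost in the opposite case. Other splits of the same libraries into groups of the same sizes, 10 in all for 3 against 3 and 35 for 4 against 4 with the real one included, gave the counts that arise by chance. Set overlaps were compared with the number from independent lists.

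Peaks per library and the share of distal peaks were compared with two-sided exact permutation tests of the difference of group means, with Benjamini-Hochberg adjustment over comparisons of the same size. With 3 libraries against 3 the smallest possible p is 0.1, and with 4 against 4 it is 0.0286. Factorial effects were permuted within the levels of the other factor, in 400 or 4900 arrangements, and interactions were tested by permuting residuals of the additive model in 100000 draws. Regions chosen in 1 experiment were scored in the libraries of another as the share holding a peak, beside control regions held by an intermediate number of the defining libraries. P-values of these tests measure the spread between libraries that the titles call biological replicates. Those of the gene lists described below come from draws of genes and carry no spread between libraries.

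The gene table gave no strand, so the planned distance to the transcription start was replaced. A peak was distal when its summit lay over 1000 bp from both ends of every protein-coding or lncRNA gene, and a region was near a gene when its centre lay within the gene or within 50 kb of it. The planned search for sequence motifs was not run because no genome sequence was used here.

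There were 14 gene lists, fixed before the data were examined: glucocorticoid receptor targets, mesenchymal and matrix genes, luminal epithelial genes, basal mammary genes, AP-1 factors, YAP and TEAD targets, NF-κB and cytokine genes, GATA and endoderm factors, SWI/SNF subunits, cell cycle genes, ribosomal protein genes, and markers of leukocytes, endothelium and neural cells. The number of list genes near a gained or lost region was compared with 10000 random lists, a permutation of genes matched on the number of regions near a gene, two-sided, with Benjamini-Hochberg adjustment over 252 tests. Named genes follow a rule also fixed beforehand. It takes 10 genes that may be given in any comparison, up to 4 members per list and direction with most changed regions, and the 8 gained and 8 lost regions with the best mean rank, named by the nearest protein-coding gene.

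The alternatives were a −log10 q of at least 5, a fold of at least 5, an equal number of best peaks per library, the summit in place of an overlap, all but 1 library in place of all, a distal distance of 2500 bp, gene windows of 10 and 100 kb, permutation within replicate numbers, and leaving out each library. Others were added after the data were seen. They were rank-matched control regions, random lists matched on the regions that could change, the exact distribution of random lists, the interaction that a general drop alone would give, region overlaps under other settings, regions shared by all libraries of a factor level, and regions lost with siGATA6 scored in the BRM014 experiment.

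The calculations were tested on simulated data. With 200 changed regions placed among the 142888 of BRM014 against DMSO, 85.5% were recovered where 85.1% were expected, none in the wrong direction. Of the unchanged regions 317 were called where 326 were expected. Presence of a changed region was drawn independently per library with a fixed high probability. The expected recovery follows from that setting and does not measure sensitivity in the real libraries. The same simulation recovered 90.5% for DEX in control siRNA, with 170679 regions and 88.6% expected, 81.0% for DEX in DMSO, with 166216 regions and 85.1% expected, and 89.0% for siBRG1_siBRM, with 128681 regions and 85.1% expected. With 3 libraries per group more unchanged regions were called, 1305 for DEX in siCtl, 1169 for siGATA6 in vehicle, 1381 for DEX in siGATA6 and 1243 for siGATA6 in DEX, and for DEX in BRM014 the number was 161. The interaction test gave p under 0.05 in 4.5% of 200 simulations without an interaction and in 81.5% with an interaction of 3 SD. Of 280 tests of random gene lists 2.14% had p under 0.05, and of 20 tests of planted lists 100% did. Analyses ran in Python 3.11.15 with NumPy 2.4.6, SciPy 1.17.1 and pandas 2.3.3.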

Results

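Accessible regions were profiled in BT549 cells in 3 experiments. In the GATA6 experiment, cells received control siRNA (siCtl) or siRNA against the transcription factor GATA6 (siGATA6) for 72 h and then vehicle or 500 nM dexamethasone (DEX), a ligand of the glucocorticoid receptor, for 2 h, with 3 libraries per group. In the BRM014 experiment, cells received DMSO or 10 µM BRM014, an inhibitor of the SWI/SNF ATPases BRG1 (SMARCA4) and BRM (SMARCA2), for 4 h, with or without 500 nM DEX for 4 h, with 4 libraries per group. In the last experiment, siRNA against both ATPases (siBRG1_siBRM) was compared with control siRNA (siCtl_only), with 4 libraries per group. The libraries held between 37184 and 131423 peaks each. Regions are given in hg38 coordinates.

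**Figure D1:**
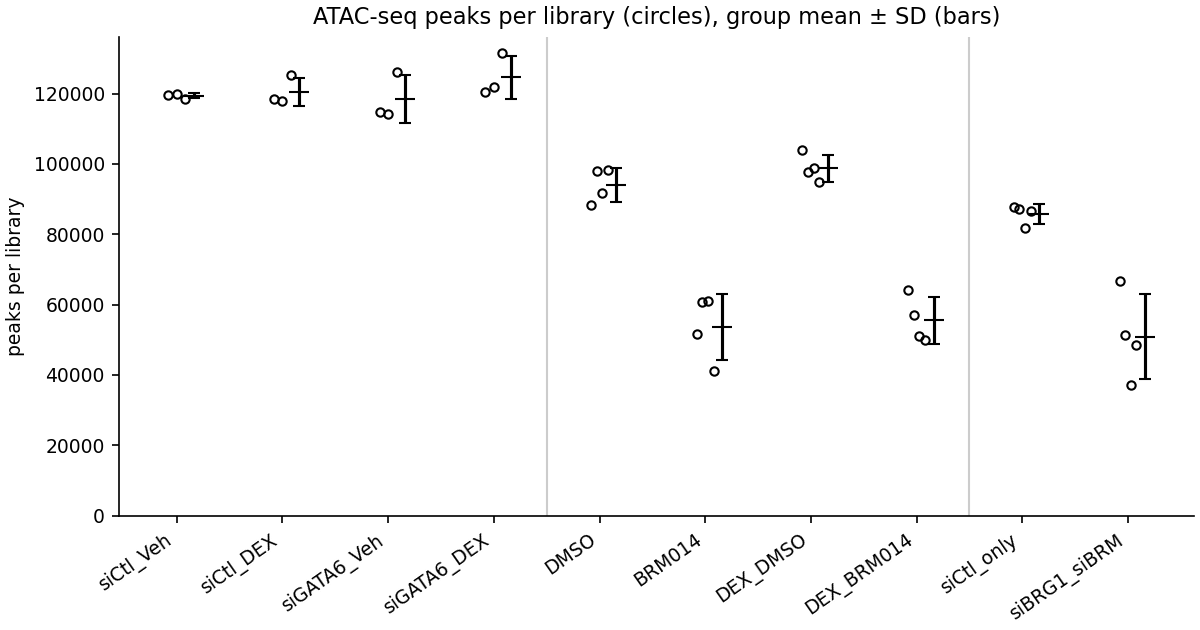
Peaks per library (vertical axis, number of peaks) in the 10 groups, with circles for libraries and bars for the group mean and SD. The BRM014 libraries lie between 41026 and 60995 peaks, under all DMSO libraries (88348 to 98220).

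The series asks how activation of the glucocorticoid receptor changes chromatin access. After 2 h of DEX in cells with control siRNA, 10 regions at FKBP5, a co-chaperone of steroid receptors, held a peak in all 3 DEX libraries and in none of the 3 vehicle libraries. ZBTB16, a zinc-finger repressor, and TSC22D3, which encodes the anti-inflammatory protein GILZ, had 8 such regions each, and ERRFI1, a feedback inhibitor of EGFR, had 7. DUSP1, a phosphatase of MAP kinases, had gained regions at 5:172772438-172772632, 5:172775525-172775844 and 5:172795308-172795784, all outside the gene. At GATA6 the gained regions lay inside the gene at 18:22199018-22199354 and outside it at 18:22214730-22215010. The gained regions with the best mean rank were at 10:72248252-72249118 near ANAPC16, at 20:53622602-53622945 near ZNF217 and inside ZBTB16 at 11:114179194-114179859. A region inside LAMA3, a laminin chain, at 18:23725655-23726227 was also among the best 8.

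Genome-wide, DEX at 2 h gained 4287 regions and lost 1392 in control siRNA, where the other 9 splits of the same 6 libraries reached at most 1413 in all. Of the gained regions 90.7% and of the lost regions 90.4% were distal, against 79.4% of all regions, and with siGATA6 in vehicle 92.3% of the gained and 87.9% of the lost regions were, so a high distal share was not particular to regions gained with DEX. The number of peaks was 120550 ± 3985 with DEX and 119341 ± 737 without (SD, n = 3 each; exact permutation p = 0.9, the smallest possible being 0.1). In siGATA6 cells DEX gained 4119 regions and lost 1040 (highest other split 1356, and 967 in one direction), with 10 gained regions at TSC22D3, 8 at FKBP5 and 5 at ZBTB16. Gained in both siRNA settings were 2221 regions, against 112 for independent lists and at most 25 in other pairs of splits. Losses recurred less, with 93 regions lost in both settings, 6.68% of the 1392 and 8.94% of the 1040 (7.78 for independent lists, at most 25 in other pairs), against 51.8% and 53.9% of the gained regions. With a −log10 q of at least 5 the 617 regions lost in siGATA6 cells lay under the highest one-direction count of other splits, 1121. With an equal number of best peaks in every library the 1310 lost there lay above it, 699. Without vehicle replicate 3 the count of changed regions in control siRNA rose to 8827, and without siGATA6_DEX replicate 1 or 2 that in siGATA6 rose to 7816 or 7868, since the rule then asked for fewer libraries.

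Of the fixed lists, the glucocorticoid receptor targets stood apart near gained regions. In control siRNA 25 of 39 tested members had a gained region (random mean 12.5; permutation p = 0.0002, the smallest that 10000 random lists can give, adjusted 0.0252). With siGATA6 the count was 23 of 39 (random mean 12.8, adjusted permutation p = 0.0756). The result in control siRNA depended on the random lists. Matched on the regions that could have been gained, a choice made after the data were seen, the adjusted p was 0.0882 from 10000 random lists and 0.0621 from their exact distribution. Other lists were not past the threshold, gained or lost, within 50 kb of a gene. Mesenchymal and matrix genes had a region lost with DEX in siGATA6 cells at 10 of 40 members (random mean 3.49, adjusted permutation p = 0.212), within 100 kb at 13 of 40 (4.56, adjusted permutation p = 0.0378) and within 10 kb at 4 of 39 (3.02, adjusted permutation p = 1). Mesenchymal and matrix genes had gained regions at 16 of 39 members, among them CALD1, ITGB1 and CDH2 with 3 each (random mean 13.9), basal mammary genes at 9 of 22, with LAMA3 and the caveolin genes CAV1 and CAV2 (6.74), luminal epithelial genes at 9 of 25, with GRHL2 and CDH1 (6.46), and YAP and TEAD targets at 12 of 24, with ASAP1 and F3 (10.0). AP-1 factors had gained regions at 5 of 13 members (random mean 4.52), NF-κB and cytokine genes at 4 of 20 (5.61), GATA and endoderm factors at 6 of 17 (4.42), SWI/SNF subunits at 6 of 28 (9.26), cell cycle genes at 8 of 32 (7.74) and ribosomal protein genes at 13 of 48 (13.6). Markers of leukocytes, endothelium and neural cells had 3 of 12 (2.96), 3 of 11 (2.59) and 2 of 10 (2.24).

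The response to DEX was then compared with that at 4 h in the BRM014 experiment. DEX gained 2526 regions and lost 728 in DMSO, where the other 34 splits reached at most 281 in all. FKBP5 had 9 gained regions, ZBTB16 8, TSC22D3 5 and KLF9, a Krüppel-like factor induced by glucocorticoids, 4. The regions of best mean rank were inside PDE4DIP at 1:148901228-148901394 and ATAD2 at 8:123405301-123405883, and the region near KLF9 at 9:70438447-70438897 was also among them. Of the regions gained at 2 h and at 4 h, 1314 overlapped, against 63.7 for independent lists, and of the lost regions 30 did, against 4.84. The gained ones were 30.7% of the first and 52.0% of the second set, and with an equal number of best peaks in every library 192 overlapped. Glucocorticoid receptor targets had a gained region at 20 of 39 members (random mean 8.26, adjusted permutation p = 0.0252). Matched on regions that could have been gained, the adjusted p was 0.0504 from 10000 random lists and 0.0390 from their exact distribution, and within 10 kb of a gene it was 0.0605 with 12 members. YAP and TEAD targets had a gained region at 10 of 24 members (random mean 6.85), mesenchymal and matrix genes at 9 of 39 (8.04) and SWI/SNF subunits at 3 of 27 (6.19), and no list but the receptor targets passed. With an equal number of best peaks in every library DEX gained 917 regions and lost 546, a smaller share of gained regions.

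The number of peaks did not differ detectably with DEX at 4 h, at 98808 ± 3831 against 94069 ± 4805 (SD, n = 4 each; exact permutation p = 0.2). The distal share of peaks was higher by 0.861 percentage points (74.0 ± 0.545% against 73.1 ± 0.473%; exact permutation adjusted p = 0.0357), but only by 0.180 points with an equal number of peaks (adjusted p = 0.343 in the same exact test).

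**Figure D2:**
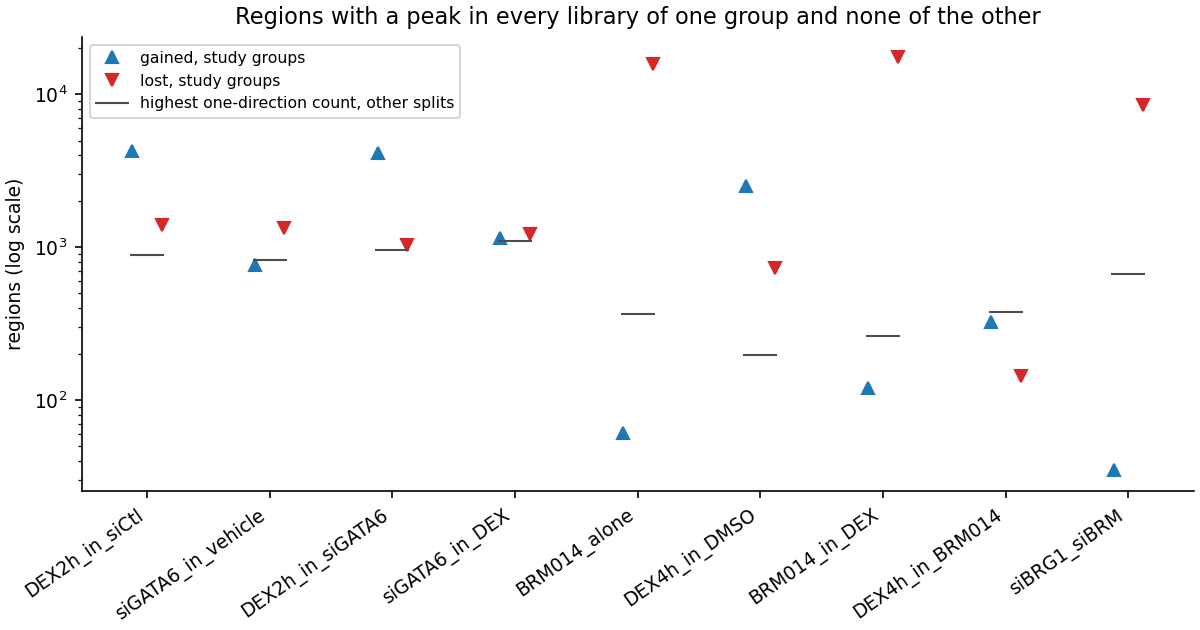
Regions gained (triangles up) and lost (triangles down) in the 9 comparisons, on a log scale, with a dash for the highest one-direction count in other splits of the same libraries. BRM014 lost 15930 regions, against at most 368 in other splits.

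The next question was what the loss of GATA6 does to access, in vehicle and in DEX. At 8:121527400-121527670 near HAS2, a hyaluronan synthase, and inside CEP83 at 12:94326706-94327096, a peak was present in all siCtl and no siGATA6 libraries in both settings. A region near KRT19, a keratin of luminal epithelium, at 17:41530176-41530477 was lost in vehicle. Outside GATA6 but near it, 18:22206957-22207353 held a peak in 3 of 3 siCtl libraries in vehicle and 3 of 3 in DEX, and in 0 of 3 and 1 of 3 siGATA6 libraries. Peaks at GATA6 do not measure its knockdown.

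In vehicle siGATA6 lost 1345 regions and gained 765 (highest total in other splits 1400), and in DEX it lost 1221 and gained 1157 (highest 1565). The 765 gained regions lay under the highest one-direction count of the other splits, 825. In DEX that count was 1100, little under the 1221 lost and 1157 gained regions. With a −log10 q of at least 5 the 1060 regions lost and 706 gained in DEX lay under theirs, 1258. With an equal number of best peaks in every library the counts lay above those of other splits. They were 772 gained and 1308 lost in vehicle (highest 735), and 875 gained and 1342 lost in DEX (749). In simulated data for these comparisons 1169 and 1243 unchanged regions were called, where the totals seen were 2110 and 2378. Both settings shared 241 lost regions, where independent lists would share 8.05 and other pairs of splits at most 30, and 48 gained regions, where the values were 4.64 and 30. Both comparisons are small and sensitive to single libraries, and in vehicle the mean background level of the siGATA6 libraries was 0.899 times that of the siCtl libraries. Leaving out any 1 of the 6 libraries raised the total to between 3715 and 4721 in vehicle and between 4184 and 4953 in DEX, since fewer libraries then have to meet the rule.

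No list passed in either setting. GATA and endoderm factors had a lost region at 3 of 17 members in vehicle (LMCD1, GATA6 and GATA5; random mean 1.58) and at 3 of 18 in DEX (ZFPM2, LMCD1 and WNT5A; 1.45). NF-κB and cytokine genes had a lost region at 4 of 24 members in each setting, with CXCL8, a neutrophil chemokine, having 2 lost regions in both. Basal mammary genes had a lost region at 4 of 22 in vehicle (2.53), where EGFR had 3, and at 1 of 22 in DEX (2.30), and a gained region at 4 of 22 in vehicle (1.43). The share of the 4 h DEX regions holding a peak was 89.4 ± 4.19% with DEX in siCtl and 87.5 ± 3.80% in siGATA6, against 21.2 ± 2.26% and 23.1 ± 3.79% in vehicle (SD, n = 3 each). The DEX effect differed between the siRNA settings by -3.66 percentage points (permutation p = 0.399).

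Inhibition of the SWI/SNF ATPases was followed by a large loss of peaks. Among the regions present in all 4 DMSO and in no BRM014 library, that of best mean rank was inside PSCA, which encodes prostate stem cell antigen, at 8:142675982-142676422. LAMA3 had 9 lost regions, GRHL2, a grainyhead factor of epithelia, 7, and TP63, a transcription factor of basal epithelium, 7. TNC, which encodes the matrix protein tenascin C, and KRT7 had 7 each, TEAD1 8, and DPF3, a SWI/SNF subunit, 13 of its 29. The region at 5:143262450-143262692 near the glucocorticoid receptor gene NR3C1 held a peak in 4 of 4 DMSO and 4 of 4 DEX_DMSO libraries and in none with BRM014. Outside SMARCA4 but near it, regions at 19:11085434-11085788 and 19:11095023-11095349 were lost in the same way, which is no measure of the ATPases themselves. A region inside NR3C1 at 5:143398998-143399158 went the other way, in 0 of 4 DMSO and 4 of 4 BRM014 libraries. With DEX it was held by 0 of 4 DEX_DMSO and 1 of 4 DEX_BRM014 libraries.

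BRM014 lowered the number of peaks from 94069 ± 4805 to 53586 ± 9441, a change of -43.0%, and with DEX from 98808 ± 3831 to 55519 ± 6573, -43.8% (SD, n = 4 each; exact permutation p = 0.0286, adjusted 0.0476, in both), and the groups did not overlap. Permuted within DEX levels, the change was -43.4% (exact p = 0.000408). The distal share of peaks changed by -9.15 points without and -9.65 points with DEX (exact permutation adjusted p = 0.0357 in both). BRM014 lost 15930 regions and gained 61, where the other 34 splits reached at most 375, and with DEX lost 17489 and gained 120 (highest 276), the gained regions lying under the highest one-direction counts of 368 and 262. Lost in both settings were 8929 regions, against 2264 for independent lists and at most 5 in other pairs of splits. With an equal number of best peaks in every library the counts were 4486 lost and 1103 gained without DEX, and 4931 and 1351 with it. In lists of equal length other peaks replace those that drop out, so part of these gains follows by construction.

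Each list had members with lost regions, and within 50 kb of a gene no list stood apart from random lists. Lost regions were near 33 of 40 mesenchymal and matrix genes (random mean 26.1, adjusted permutation p = 0.549), 19 of 24 luminal epithelial genes (14.8), 12 of 13 AP-1 factors such as ATF3 and JUND (8.82), and 21 of 24 YAP and TEAD targets such as ASAP1 and CRIM1 (17.5). NF-κB and cytokine genes such as LIF had lost regions at 19 of 24 members (13.9), basal mammary genes at 13 of 20 (12.8), SWI/SNF subunits at 18 of 28 (18.7) and GATA and endoderm factors at 8 of 17 (10.0). Near glucocorticoid receptor targets they were found at 27 of 40 (random mean 26.3), near ribosomal protein genes at 24 of 48 (30.2) and near cell cycle genes at 19 of 34 (19.7). Within 10 kb, ribosomal protein genes had a lost region at 4 of 48 members, fewer than the random mean of 14.5, with an adjusted p of 0.0504 from 10000 random lists and 0.0273 from their exact distribution. With DEX present, ZBTB16 had 14 lost regions, LAMA3 and the P-cadherin gene CDH3 10 each, and FKBP5 and DUSP1 6 each, and receptor targets had a lost region at 33 of 40 members (28.0). The few gained regions included 11:10507892-10507962 near AMPD3 and 6:21596773-21596941 in SOX4.

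The question whether DEX still opens chromatin under the inhibitor was put to the regions gained at 2 h in the GATA6 experiment, which were chosen without the libraries scored here. Of these 4287 regions, 55.5 ± 1.83% held a peak in DEX_DMSO, 3.38 ± 0.625% in DMSO, 6.92 ± 2.27% in DEX_BRM014 and 1.43 ± 0.786% in BRM014 (SD, n = 4 each). The DEX effect differed between BRM014 and DMSO by -46.6 percentage points (interaction, permutation p = 0.00018). Since few of these regions held a peak without DEX, a loss at the rate of other regions would alone give a negative value, -32.2 points at the rate of rank-matched and -37.7 at that of control regions. Control regions held a peak in 21.3 ± 3.60% of cases in DMSO, 22.7 ± 2.24% in DEX_DMSO, 5.55 ± 2.94% in BRM014 and 6.26 ± 2.36% in DEX_BRM014 (SD, n = 4 each; exact permutation p = 0.0286 for BRM014 against DMSO). Rank-matched regions, chosen after the data were seen like these expected values, had 61.1 ± 2.40% in DEX_DMSO and 23.3 ± 3.91% in DEX_BRM014. They were drawn from regions held by every siCtl_DEX and every siCtl_Veh library, so they differ from the DEX regions in holding a peak without DEX. In DMSO they had 65.6 ± 5.14% and in BRM014 23.1 ± 7.62%. At FKBP5 each of the 9 regions gained at 4 h in DMSO was held by fewer than 4 DEX_BRM014 libraries, and 5 were held by none. By contrast 9:70438447-70438897 near KLF9 and 5:172766583-172766910 near DUSP1, in no DMSO and 4 of 4 DEX_DMSO libraries, and 11:114179194-114179869 in ZBTB16, in 1 and 4, were held by 4 of 4 DEX_BRM014 libraries.

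Changes with DEX in the presence of the inhibitor were fewer. DEX gained 323 regions and lost 145, where the other 34 splits reached at most 383, and the region near ZNF217 at 20:53622614-53622926 had the best mean rank. The 323 gained and the 145 lost regions lay under the highest one-direction count of the other splits, 376, and the simulation called 161 unchanged regions here. Leaving out BRM014 replicate 2 or 4 or DEX_BRM014 replicate 3 or 4 gave 758, 945, 719 and 797 changed regions. With an equal number of best peaks in every library DEX gained 270 regions and lost 227, above the highest one-direction count of other splits, 70. Glucocorticoid receptor targets had a gained region at 8 of 39 members (random mean 1.38, adjusted permutation p = 0.0336), BIRC3, an inhibitor of apoptosis, having 2. Matched on regions that could have been gained the adjusted p was 0.0504 from 10000 random lists, the smallest that this number of draws allowed it, and 0.0175 from their exact distribution. Regions gained with DEX in DMSO held a peak more often in DEX_BRM014 than in BRM014, at 9.36 ± 3.16% against 1.97 ± 1.23% (SD, n = 4 each; exact permutation p = 0.0286).

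**Figure D3:**
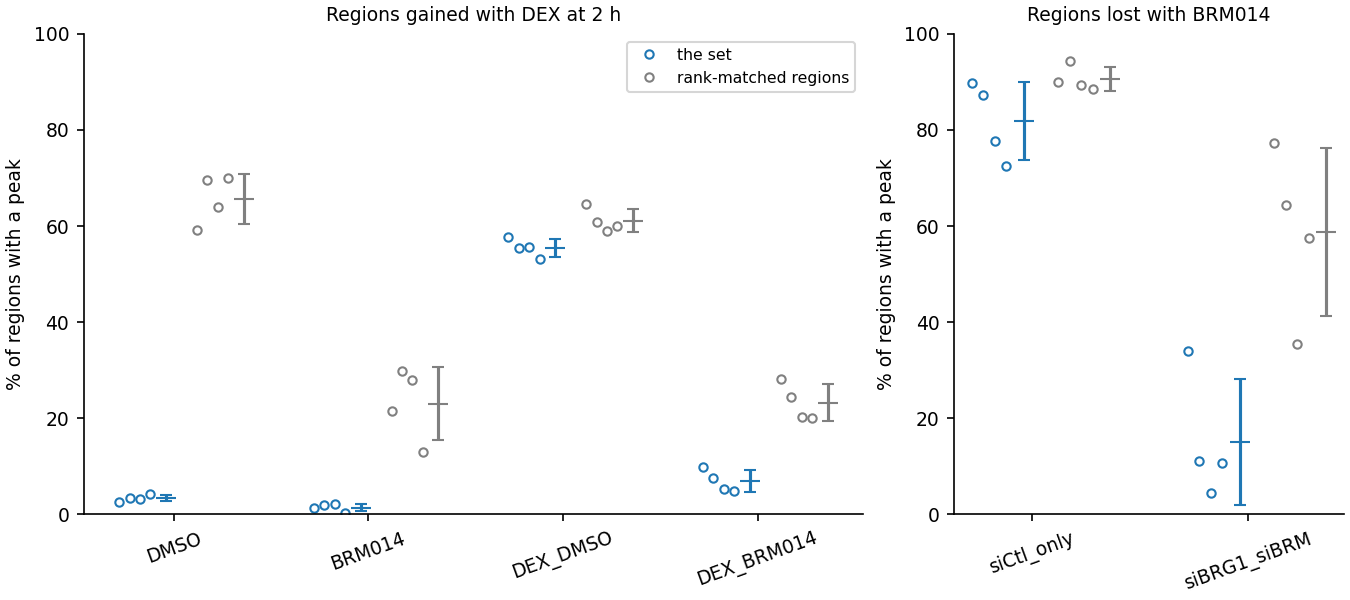
Share of regions holding a peak (vertical axis, %) for regions gained with DEX at 2 h, scored in the BRM014 experiment, and regions lost with BRM014, scored in the experiment with siRNA against both ATPases, with the set in blue, rank-matched regions in grey, circles for libraries and bars for mean and SD. The 2 h regions reach 55.5% with DEX in DMSO and 6.92% with DEX in BRM014. Rank-matched regions of the BRM014 set had to keep a peak in some BRM014 library. Those of the 2 h set were held by every defining library, with and without DEX.

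**Figure D4:**
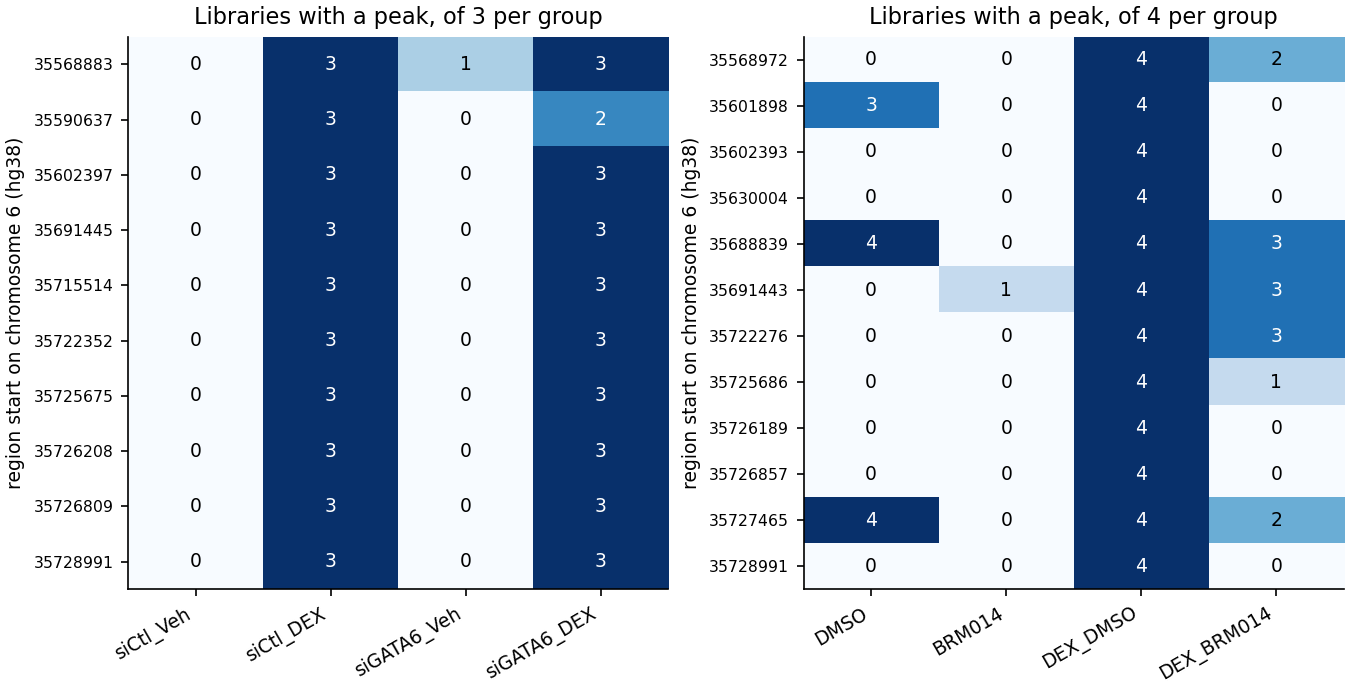
Number of libraries with a peak at changed regions of FKBP5 on chromosome 6, by region start in hg38 coordinates, in the GATA6 experiment (3 libraries per group) and the BRM014 experiment (4 per group). The region at 35728991 was held by 4 of 4 DEX_DMSO libraries and none with BRM014.

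Knockdown of both ATPases was compared with the inhibitor. TNFRSF11B, which encodes osteoprotegerin, had the lost region of best mean rank at 8:118905234-118905519, and next were 21:15706740-15707139 near USP25 and 20:62703585-62703827 near the neurotensin receptor gene NTSR1. LAMA3 had 4 lost regions, TP63 3, GRHL2 3, TNC 3 and ASAP1 6. At NR3C1, 5:143262451-143262704 held a peak in 4 of 4 siCtl_only and no siBRG1_siBRM libraries, and 19:11085423-11085780 and 19:11094979-11095357 near SMARCA4 went from 4 of 4 to 0 of 4 libraries.

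siBRG1_siBRM lowered the number of peaks from 85769 ± 2782 to 50934 ± 12122, a change of -40.6% (SD, n = 4 each; exact permutation p = 0.0286, adjusted 0.0476), and the distal share changed by -9.10 points (exact permutation adjusted p = 0.0357). It lost 8503 regions and gained 35, where the other 34 splits reached at most 680. Without replicate 1 of siBRG1_siBRM, which had 66607 peaks, the count of changed regions was 15333. With an equal number of best peaks it lost 2566 and gained 759, where part of the gains again follows from lists of equal length. No list passed. Luminal epithelial genes had lost regions at 16 of 24 members, such as KRT19 and ELF3 (random mean 10.1, adjusted permutation p = 0.549), mesenchymal and matrix genes at 22 of 40 (18.4), YAP and TEAD targets at 15 of 24 (13.2), glucocorticoid receptor targets at 17 of 39 (17.1), SWI/SNF subunits at 11 of 28 (13.1) and AP-1 factors at 6 of 13 (6.64).

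Regions lost with siBRG1_siBRM and with BRM014 overlapped at 4866, against 1258 for independent lists, at 7615 without replicate 1 of siBRG1_siBRM and at 1400 with an equal number of best peaks. Those were 57.2% of the siRNA set and 30.5% of the inhibitor set. Scored in the other experiment, regions lost with BRM014 held a peak in 81.8 ± 8.10% of cases in siCtl_only and 15.1 ± 13.0% in siBRG1_siBRM (SD, n = 4 each; exact permutation p = 0.0286, adjusted 0.0343). Control regions went from 53.4 ± 4.48% to 24.6 ± 12.1%. Regions lost with siBRG1_siBRM went from 89.5 ± 1.89% in DMSO to 9.55 ± 4.50% in BRM014, and their control regions from 70.8 ± 6.24% to 30.7 ± 13.4%. Rank-matched regions of this set went from 94.0 ± 2.25% to 58.7 ± 13.3%. They had to keep a peak in at least 1 siBRG1_siBRM library, so part of their smaller loss may follow from that choice.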

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

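The counts of splits, the depth test for BRM014, the depth tests of siGATA6 at each DEX level, the interaction that a general drop would give, the comparison of DEX regions with control regions and the test of lost regions in the upper rank range against splits with a wider background gap were chosen after the results were seen. For depth under siBRG1_siBRM an earlier reading, which also asked for treated libraries at or above the mean background of the others, left the matter undecided, and a second reading was dropped because its bound was set at the value seen. The split test then took their place for all depth explanations, with a bound of 5 times. For the general drop of DEX regions a looser reading than the bounds written beforehand was tried and dropped.

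Replicate 3 of siCtl_only had 81639 peaks against 86631 to 87609 in the other libraries of its group, a gap of 0.836 of the group's range. It was the only such library among 28 groups of 4 values, where chance marks about 1 in 20 groups, or 1.4 here.

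Fewer peaks were called with BRM014 and with siBRG1_siBRM. Lower depth is argued against by ratios of background levels of 1.00 and 0.960. Lost regions in the upper rank range numbered 5968 and 2502, where splits with a wider background gap reached at most 3 and 7. Those splits hold treated and control libraries on both sides, so any cause shared by the treated libraries gives low counts there. They bear only on depth as the background level measures it. The lowest background was shared by fewer weak peaks with BRM014 (22.5 ± 6.98%) than in DMSO (43.5 ± 3.62%). For siBRG1_siBRM the share was 23.5 ± 9.10%, against 36.3 ± 5.41% in siCtl_only. The ratios of lowest levels do not capture this difference in local background. A drop of signal that keeps the ranking of regions is argued against by equal-number lists, in which regions lost with BRM014 were 46.7 times the highest one-direction count of other splits. For a uniform drop the bounds written beforehand left the matter undecided, and that value was not part of them. It argues against a uniform drop only as far as such a drop keeps the ranking. Whether the difference in local background altered the ranking was not tested. With BRM014 alone distal regions lost peaks 1.57 times as often as rank-matched proximal ones, with a lowest library of 1.39 under the bound of 1.5. The ratio was 1.65 for BRM014 in DEX (libraries from 1.55 to 1.76) and 1.85 for siBRG1_siBRM (from 1.58 to 2.11). However, comparisons without a fall in peaks gave ratios up to 1.71. Regions lost with BRM014 dropped by 37.9 percentage points more than control regions under siBRG1_siBRM. Control regions started lower in siCtl_only, at 53.4% against 81.8%, so part of that excess follows from the baseline. Against rank-matched regions, at 90.6% in siCtl_only, the excess was 34.8 points, with a lowest library of 22.3. Those had to keep a peak in some BRM014 library, so part of this excess may follow from that choice. Lower activity of the ATPases may account for part of the loss, which stays a hypothesis.

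The DEX effect on the 2 h DEX regions differed between BRM014 and DMSO by -46.6 percentage points in a test of the interaction, which marked it as a difference between groups. A general drop of regions of the same rank cannot be told apart from a specific one. DEX regions dropped 1.42 times as much as matched regions, between the bounds of 1.2 and 1.5, with libraries from 1.35 to 1.53. They dropped 1.22 times as much as control regions, with libraries from 1.12 to 1.41. The upper bound, asked of every library, could not have been met. Matched regions dropped by 67.0 and 67.2% in DEX_BRM014 replicates 3 and 4. Even a loss of every DEX region would have stayed under 1.5 times there, so this test could not exclude a general drop. A smaller response to DEX under the inhibitor stays open too, since DEX regions held few peaks without DEX and a general drop alone would give an interaction of -32.2 points at the rate of matched regions or -37.7 at that of control regions.

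Regions lost with siGATA6 in vehicle and in DEX numbered 241, where other pairs of splits shared at most 30, which argues against noise at the peak threshold. In DEX lower depth is argued against by a background ratio of 1.00. Lost regions in the upper rank range numbered 78 there, where splits with a wider background gap reached at most 3. Those splits mix siCtl and siGATA6 libraries on both sides, so they bear only on depth as the background level measures it. In vehicle lower depth cannot be told apart from an effect of siGATA6. There the background ratio of 0.899 met the bound of 0.9 written for depth (0.950 over both DEX levels). Lost regions in the upper rank range numbered 77, against at most 2 in the 2 splits with a wider gap, which are mixed in the same way. Loss of GATA6 may account for some of the regions lost in DEX, which stays a hypothesis, and for the vehicle libraries depth remains open beside it.

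In the experiments with 4 libraries per group 1 of 35 splits, the real one, gave as many changed regions. That share is the smallest that 35 splits allow, so chance assignment of libraries to groups is argued against but not excluded. The totals were 15991 for BRM014 alone (highest other split 375), 3254 for DEX in DMSO (281), 17609 for BRM014 in DEX (276) and 8538 for siBRG1_siBRM (680). For DEX in BRM014 the total of 468 stood close to the highest other split, 383. Its 323 gained regions lay under the 376 of another split, so in the main setting their count alone does not exclude chance. With an equal number of best peaks 270 gained and 227 lost regions stood above the highest one-direction count, 70. With a −log10 q of at least 5 the 260 gained lay above 248 and the 145 lost under it. DEX in DMSO shared 45 of the 323 gained regions, where other pairs of splits shared at most 3. In the GATA6 experiment 10 splits are too few for a share under 0.05, with 5679 for DEX in siCtl (highest other 1413), 5159 for DEX in siGATA6 (1356), 2110 for siGATA6 in vehicle (1400) and 2378 for siGATA6 in DEX (1565).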

How the results depend on the processing

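Of 211 values recomputed under other settings 180 kept their direction, side of the threshold and, where untested, size, while 9 fell short of the threshold, 5 newly passed it, 16 changed in size and 1 reversed. Of 532 with a library left out 496 stayed so and 36 changed in size. The tests of overlaps under other settings and the other ways of drawing random lists were chosen after the data were seen. Asking for all but 1 library of a group raised the changed regions by construction, to 14862 for DEX in siCtl, 9157 for siGATA6 in vehicle, 14138 for DEX in siGATA6, 9909 for siGATA6 in DEX, 7077 for DEX in DMSO, 1789 for DEX in BRM014 and 14862 for siBRG1_siBRM. With an equal number of best peaks the totals were 5589 for BRM014, 1463 for DEX in DMSO, 6282 for BRM014 in DEX and 3325 for siBRG1_siBRM, the overlaps were 192 for DEX at 2 h and 4 h and 1400 for siBRG1_siBRM and BRM014, and the DEX effect on 4 h regions was 28.6 points in siCtl and 27.5 in siGATA6, with shorter lists by construction. The distal share for DEX in DMSO lost its call, at 0.893 points with a −log10 q of at least 5 and 0.180 with equal numbers. The effect of BRM014 alone on 2 h DEX regions, -1.95 points, was -0.871 with the stricter q and 0.398 with equal numbers, the opposite direction and past the threshold (adjusted exact permutation p = 0.0312), and the cause was not tested.

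For glucocorticoid receptor targets, 10 kb windows gave 16 for DEX in siGATA6 (now past the threshold, adjusted permutation p = 0.0336) and 12 for DEX in DMSO (no longer, 0.0605; 0.0572 from the exact distribution). At 10 kb ribosomal protein genes near regions lost with BRM014, 4, passed in the exact distribution (0.0273). At 100 kb mesenchymal and matrix genes near regions lost with DEX in siGATA6, 13, passed (0.0378; 0.0390 exact), and at 10 kb, with 4, they did not. Random lists matched on regions that could change left 0 list tests past the threshold in 10000 draws, with 25 (0.0882), 20 (0.0504) and 8 (0.0504) members, the last fixed by the number of draws and so no evidence against that list, and their exact distribution left 2, DEX in siCtl with 25 not passing at 0.0621. The exact distribution was added after the draws had passed no list, so both are given.

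Leaving out single libraries gave totals of 7560 to 8827 for DEX in siCtl, 3715 to 4721 for siGATA6 in vehicle, 7158 to 7868 for DEX in siGATA6, 4184 to 4953 for siGATA6 in DEX, 639 to 945 for DEX in BRM014 and 8654 to 15333 for siBRG1_siBRM, overlaps of 4877 to 7615 for siBRG1_siBRM and BRM014, and effects on 4 h regions of 61.4 to 69.7 points in siCtl and 58.3 to 66.7 in siGATA6. Permuting within replicate numbers as a block kept the value for BRM014 at -43.0% but its exact test can reach only p = 0.125 with 4 pairs, so it decides no call. Pairing by replicate number was weak and differed between experiments. In the GATA6 experiment correlations of deviations between libraries of the same number were all positive, from 0.00924 to 0.101. There 6 of 12 libraries correlated best with their own number. Replicate 3 had the highest values, from 0.0545 to 0.101, so a weak pairing is not excluded, and the unpaired tests do not use it. Correlations ran from -0.0174 to 0.0684 in the BRM014 experiment, with 2 of 16 libraries. With siRNA against BRG1 and BRM they ran from -0.0504 to 0.0297, with 3 of 8. A summit inside the region changed no gained or lost count, by construction. The motif window could not be run. Depth limits what weak peaks show.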

Other observations

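The scoring of siGATA6 regions in the BRM014 experiment was chosen after the data were seen. Of the 241 regions lost with siGATA6 in vehicle and in DEX, 63.7 ± 5.93% held a peak in DMSO and 5.60 ± 2.38% in BRM014 (SD, n = 4 each; exact permutation p = 0.0286), while rank-matched regions went from 64.0 ± 6.55% to 22.1 ± 7.92%. With DEX the share was 49.3 ± 4.01%, lower than in DMSO in an exact permutation test (p = 0.0286), and rank-matched regions had 65.8 ± 2.10%. The 241 regions include those near HAS2 and in CEP83. The rank-matched regions were drawn from those held by every library of the GATA6 experiment, siGATA6 included. Control regions went from 23.1 ± 4.91% in DMSO to 6.58 ± 3.40% in BRM014. Regions lost with siGATA6 and with BRM014 overlapped at 148 in vehicle (125 for independent lists) and 166 in DEX (111). Regions lost with BRM014 held a peak in 97.4% of cases in siCtl_Veh, 95.5% in siGATA6_Veh, 94.7% in siCtl_DEX and 93.7% in siGATA6_DEX.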
